A study of Arabidopsis thaliana with 6 samples.

How the data were processed

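RNA from 6 suspension-culture samples of *Arabidopsis thaliana* Ler-0 was analysed, 3 treated with conditioned medium (CM) and 3 with fresh medium (BG), with the group and number of each taken from the sample titles. Per the labels' protocols, messenger RNA was bound to poly-dT beads and made into libraries with a NEBNext Ultra kit; no strand marking is stated there. Per the submitters' processing notes, HISAT2, DESeq2 and the TAIR10 build were used, with no versions given; the counting program, its strand setting and the annotation release are not given in the sources used here. Without strand, a gene and an overlapping or antisense neighbour cannot be told apart. The authors deposited raw read counts per gene for 34218 gene rows, with 11191 rows at 0 in every library. The authors deposited FPKM values for the same genes, scaled by a gene length and by each library's total. The authors deposited a comparison table with a log2 fold change, a p-value and an adjusted p-value per gene, in which the adjusted p-value is empty for 15243 genes. Gene names and descriptions come from the deposited tables, and 32548 identifiers also matched a symbol in a reference table of the assembly TAIR10.1, used only for names; 23 names that had the form of dates were replaced with it. No coordinates are given, since that assembly differs by name from the authors' build.

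Genes with enough reads were kept with filterByExpr, which left 17868, and libraries were scaled with TMM factors. The test was edgeR's quasi-likelihood F test with robust dispersion, two-sided, with Benjamini-Hochberg adjustment over the tested genes and a threshold of 0.05. The standard error of a log2 fold change is its absolute unshrunk value divided by the square root of F. CPM values are on TMM-scaled library sizes. For a gene with no read in BG a lower bound against 3 reads over the group is given; its fitted fold change, which depends on the prior count, is not given but entered the ranking of the named genes; such bounds and intervals cover counting error only. The 25 gene lists (580 entries) were fixed before the data were examined, as were the tests and the rule for named genes. Lists were tested with camera on voom values, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over lists. The alternative with an estimated correlation used the fit without the replicate number. Its correlations therefore include any spread shared by libraries of the same number. Annotation terms were families by gene-name stem and words or word pairs of descriptions, with 10 to 500 tested genes, tested against all tested genes by one-sided Fisher's exact tests, 2476 in all with Benjamini-Hochberg adjustment. The versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

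The named genes were the 10 largest rises and 10 largest falls among called genes with a mean of at least 1 CPM in the higher group and all libraries of one group above the other; in each list the 2 called members with the largest absolute change, 4 in 6 lists, or the smallest p where none was called; 12 genes named in advance; and up to 3 members of an enriched term. A few genes outside it were chosen after their values were seen: MGD3, CESA8, TIP41, WRKY70, ERF104, CYP79B3, CAD4, GVPE, CML23, CDC20.1, AGP7, FLA1, FLA8, NIA1, HHO2, IAA19, FRO2, CKX4, and the clock genes LHY and GI. The values of 1 list gene are not reported here. Same-numbered libraries deviated together after the group means were removed, with correlations of 0.611, 0.394 and 0.636 for pairs 1, 2 and 3, so the numbers were taken to pair the libraries and a fit with the number as a block is given beside the list counts it changes. This pairing comes from the data and the shared numbers in the titles, not from a stated shared culture or day. The main fit has no block, as planned, so its p-values include spread that the replicate numbers share across groups. Leaving out a single library also breaks a pair. Same-group libraries differed by a chi-square per gene of 16.8 to 103.1, beyond sampling noise, so none was counted as a duplicate. On simulated counts with 200 changed genes among 17728, the test recovered 43% of the 2-fold and 88% of the 4-fold changes, with 8 false calls among 139. The simulation had few changed genes, in equal numbers up and down, and no effect shared by replicate number or shift in composition. The shares recovered are therefore not the power of the test in these data. Alternatives covered scaling, filters, DESeq2, limma-voom, limma on log2(FPKM + 1) and log2(FPKM + 0.1), thresholds, the replicate block and leaving out each library.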

Results

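Poly(A)-selected RNA was sequenced from undifferentiated *Arabidopsis thaliana* suspension cells of the accession Ler-0, 7 days old at treatment. The cells had been incubated for 1 h with 20% v/v medium in which the nitrogen-fixing cyanobacterium *Nostoc punctiforme* had grown (conditioned medium, CM). Control cells received 20% v/v of the fresh cyanobacterial growth medium, BG-11(NH4) (BG). Each of the 2 groups had 3 libraries, numbered 1 to 3 and named BG1 to BG3 and CM1 to CM3 below. The labels do not say whether libraries came from separate cultures, so p-values measure the spread between these libraries, part of which may be technical. Purely technical spread is argued against by the clock genes LHY and GI. Their log2 difference spanned 5.07 within BG and 5.13 within CM, and rose from replicate 1 to replicate 3 in both groups. The libraries held between 16430301 and 18630256 counted reads. By library size, without TMM scaling, a count of 3 reads corresponded to between 0.161 and 0.183 CPM. The comparison asks which transcripts differ between conditioned and fresh medium, in a study of defence genes and programmed cell death. With fresh medium as the control, compounds released by the cyanobacterium cannot be told apart from nutrients that its growth used up.

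Cells in conditioned medium differed from control cells in many transcripts. Of 17868 genes tested, 2653 were higher and 2458 lower in CM (edgeR quasi-likelihood test, adjusted p under 0.05), and 1416 of the first and 1147 of the second changed by at least 1 on the log2 scale. All 3 libraries of one group lay above all 3 of the other for 46.8% of the tested genes, where chance gives 10%. The first principal component of log2 CPM held 71.3% of the variance and separated the groups. The second held 17.2% and set replicate 3 of both groups apart from replicates 1 and 2. Without replicate 3 in both groups, 2588 genes were higher and 2177 lower, and without CM2 1524 were lower. With the replicate number as a block, 4198 genes were higher and 4518 lower.

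The balance of higher and lower calls depended on the scaling of the libraries. With library size alone in place of TMM factors, 1677 genes were higher and 6196 lower, and the median log2 fold change moved by -0.32. Higher calls made up 51.9% of calls with TMM and 21.3% with library size alone. In the authors' deposited table, 1874 genes were higher and 5158 lower at an adjusted p under 0.05. Fold changes in the authors' deposited table differed by a median of -0.28 in log2 from DESeq2 with its default size factors and of 0.057 from DESeq2 with library-size factors; the scaling used there is not given in the sources used here. Of the calls made here, 1769 higher and 2456 lower ones were shared with the authors' deposited table, and 0 genes were called in opposite directions. Fold changes below are relative to TMM scaling. Mitochondrially encoded transcripts took 0.126% ± 0.0529 of reads in BG and 0.577% ± 0.234 in CM (SD, n = 3), and plastid-encoded transcripts 0.00908% ± 0.00212 and 0.0425% ± 0.0153. An exact permutation test of either share gave p = 0.1, the smallest that 3 libraries against 3 allow.

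**Figure D1:**
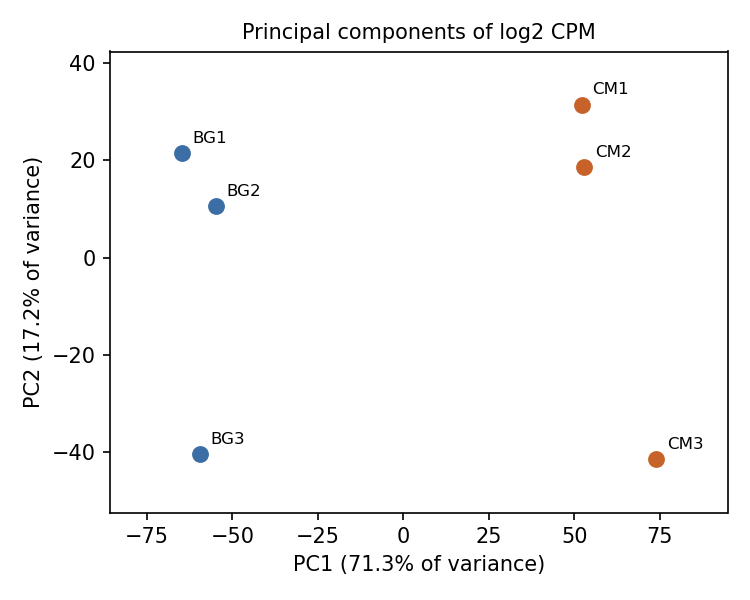
Libraries on the first 2 principal components of log2 CPM, in arbitrary units, with blue points for BG and orange points for CM. The first component (71.3% of the variance) separates the groups, and the second (17.2%) sets replicate 3 of each group apart.

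**Figure D2:**
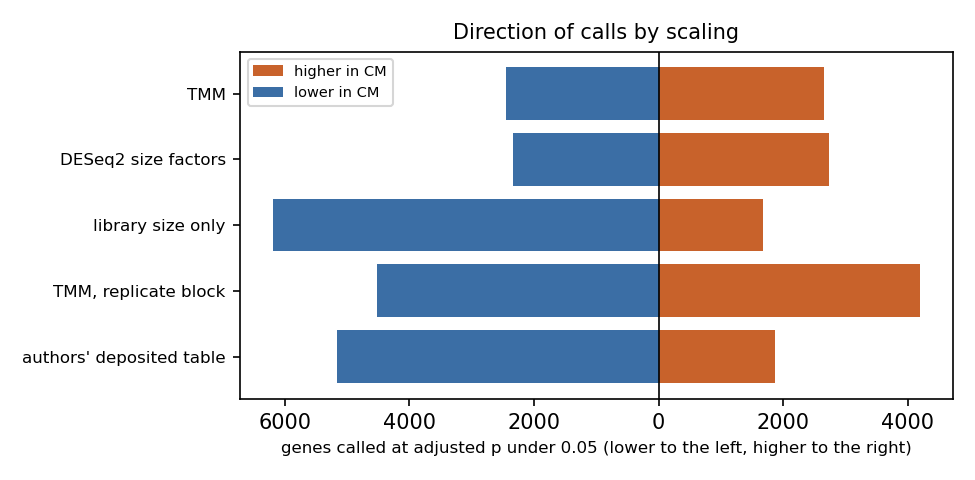
Number of genes called lower (left, blue) and higher (right, orange) in CM at an adjusted p under 0.05, by scaling, with the replicate block, and in the authors' deposited table. With TMM 2653 genes were higher and 2458 lower; with library size alone 1677 were higher and 6196 lower.

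Several genes with large rises were nearly silent in BG. AT5G40590 had no read in any BG library and reached 12.1 ± 1.76 CPM in CM (SD, n = 3), at least 235-fold higher against a floor of 3 reads over the BG group. AT2G27320, AT3G23123, AT2G36690, AT4G06290 and the cytochrome P450 gene CYP715A1 (AT5G52400) also had no BG read, and their lower bounds ranged from 21.7-fold to 77.8-fold, which does not show that they rose more than other genes named below. AT1G07160, annotated as the PP2C-type phosphatase AP2C2, rose from 0.186 ± 0.0671 to 32.0 ± 6.74 CPM (log2 fold change 7.36 ± 0.30 SE, adjusted p = 0.000183). The berberine bridge enzyme-like gene AT1G30700 rose by 7.59 ± 0.74, AT2G25735 by 8.22 ± 1.31 and AT5G12340 by 7.16 ± 0.67 on the same scale. Among the largest falls, the heat stress transcription factor gene HSFB4 (AT1G46264) dropped from 39.8 ± 3.52 to 1.201 ± 0.726 CPM (log2 fold change -5.05 ± 0.34, adjusted p = 0.000445). FAF4 (AT3G06020) fell by 5.40 and AT1G11700 by 5.61 on the log2 scale. ERF003 (AT5G25190), GDU3 (AT5G57685), IBL1 (AT4G30410), AT2G34620, AT3G61750, AT2G16580 and MYB59 (AT5G59780) had log2 fold changes between -4.77 and -4.41. The call for MYB59 was lost with limma-voom (adjusted p = 0.0829) and without CM1, CM2 or CM3 (adjusted p from 0.0603 to 0.0873 with edgeR).

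Genes of early immune signalling rose as a group. By the share of higher calls over all tested genes, 5.0 rises would be expected in this list. Of 34 measured members of a list of pattern-recognition receptors, kinases and early response genes, 28 rose and 6 did not pass (29 rose when adjusted over the list alone; 30 rose and 2 fell with the replicate block; 25 rose and 1 fell with library size alone; 1 fell without BG3), and the list median was 1.57 in log2 fold change. PROPEP3 (AT5G64905), which encodes the precursor of an endogenous danger peptide, rose from 6.41 ± 4.98 to 566.8 ± 404.7 CPM (6.47 ± 0.82 SE). PROPEP2 (AT5G64890), PROPEP1 (AT5G64900) and FRK1 (AT2G19190), a flagellin-responsive receptor kinase gene, rose by 6.29 ± 0.86, 5.18 ± 1.05 and 6.08 ± 0.53. Their BG levels were 0.142 ± 0.131, 0.0714 ± 0.0855 and 0.0677 ± 0.0246 CPM, so the sizes of these rises rest on few BG reads. The flagellin receptor gene FLS2 (AT5G46330) rose from 20.8 ± 4.005 to 189.9 ± 18.2 CPM, and the chitin receptor gene CERK1 (AT3G21630) from 47.7 ± 10.8 to 430.0 ± 104.4 CPM. RBOHD (AT5G47910), the oxidase of the immune oxidative burst, rose by 2.18 ± 0.44 (adjusted p = 0.0117). The list stood above other genes by camera with a preset correlation (adjusted p = 1.73e-12), and its adjusted p was 0.455 with an estimated correlation.

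Many WRKY transcription factor genes rose. In the WRKY list 4.0 rises would be expected by the share over all tested genes. Of the 43 tested genes with a WRKY name, 20 were higher. Of 27 measured members of the WRKY list, a part of that family, 19 rose and 1 fell (20 and 2 when adjusted over the list alone), with a median log2 fold change of 1.501; with the replicate block 21 rose and 2 fell, and with library size alone 18 rose and 3 fell. WRKY30 (AT5G24110) rose from 2.18 ± 0.726 to 189.9 ± 23.1 CPM (6.45 ± 0.27 SE), and WRKY72 (AT5G15130), WRKY41 (AT4G11070) and WRKY8 (AT5G46350) rose by 5.58, 4.15 and 4.09. WRKY72 was at 0.138 ± 0.149 CPM in BG, so the size of its rise rests on few reads there. WRKY33 (AT2G38470), WRKY40 (AT1G80840) and WRKY53 (AT4G23810) rose by 2.37 ± 0.30, 2.07 ± 0.26 and 1.58 ± 0.28. The fall was that of WRKY70, at -3.47, a gene picked out after its value was seen and which a filter of at least 1 CPM in 3 libraries leaves out. The camera adjusted p was 4.56e-09 with a preset correlation and 0.455 with an estimated correlation.

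**Figure D3:**
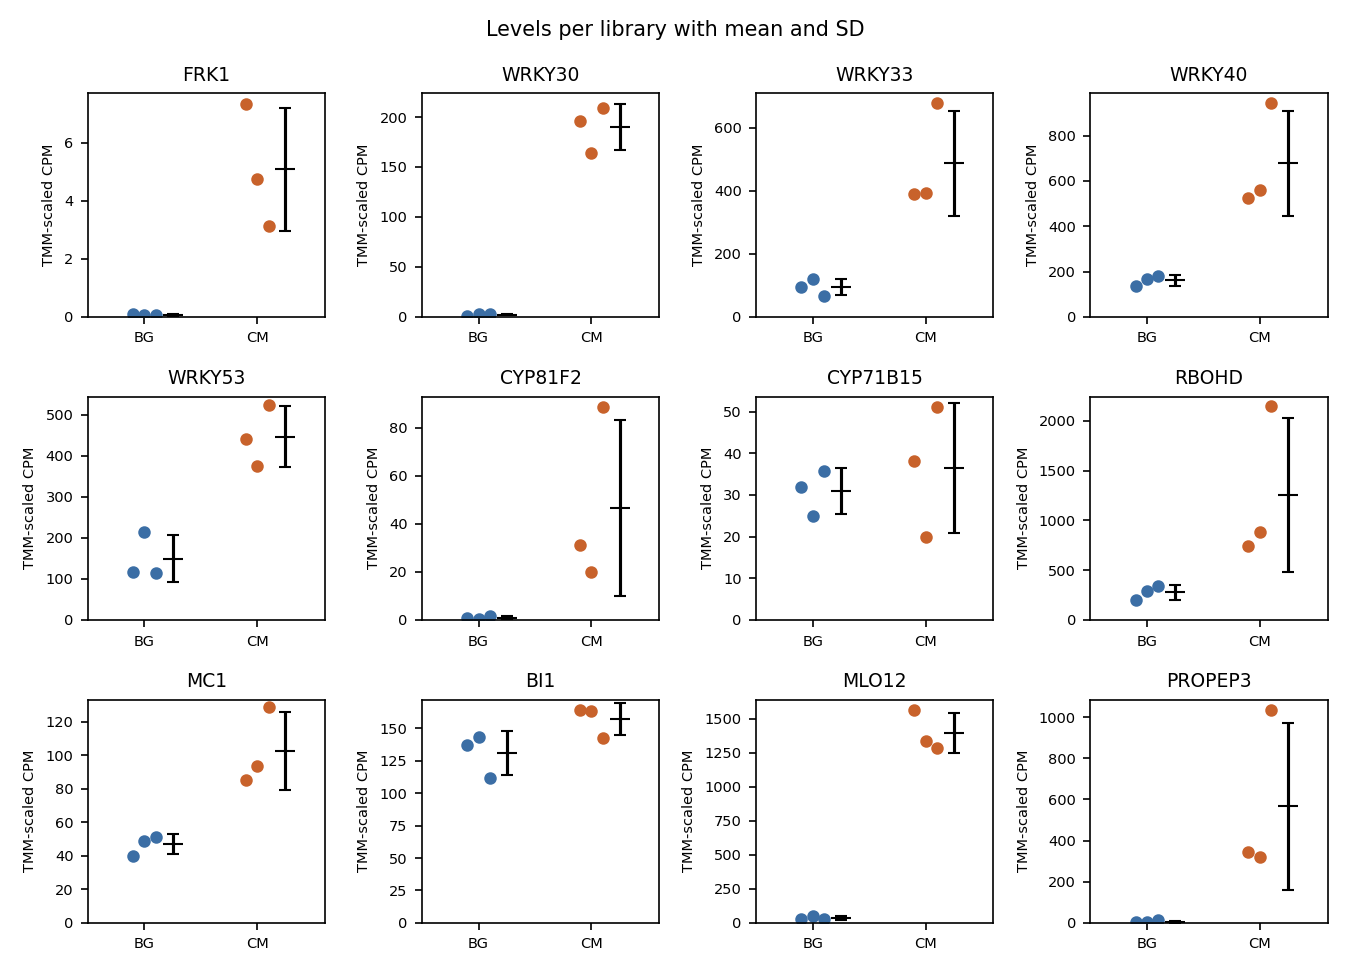
TMM-scaled CPM of 12 genes in each library (points, BG in blue and CM in orange) with the mean and SD of 3 libraries beside them, on linear axes that start at 0. WRKY30 rose from 2.18 to 189.9 CPM, whereas CYP71B15 and BI1 did not pass the test.

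Hormone-related lists held calls in both directions. By the shares of calls over all tested genes, 2.7 rises would be expected in the salicylic acid list, 3.7 in the ethylene list and 3.1 in the jasmonate list. The falls expected were 2.5, 3.4 and 2.9. Of 18 measured members of the salicylic acid list, 9 rose and 1 fell (9 and 2 when adjusted over the list alone; 11 and 2 with the replicate block; 5 and 3 with library size alone; 2 fell without CM3), with EDS5 (AT4G39030), a transporter needed for salicylic acid synthesis, at 3.89 ± 0.42, the immune regulator gene EDS1 (AT3G48090) at 1.71 ± 0.26 and DMR6 (AT5G24530) at 1.36 ± 0.24. EPS1 (AT5G67160), which acts in salicylic acid synthesis, fell from 26.8 ± 15.6 to 1.84 ± 0.817 CPM (-3.87 ± 0.50). The camera adjusted p was 0.0243, against 0.477 with an estimated correlation, and 0.0576 without BG1. No read of PR1 (AT2G14610), a marker of the salicylic acid response, or of PDF1.2 (AT5G44420), a marker of the jasmonate and ethylene response, was counted in any library, so neither was detectable at this depth. In the ethylene list 6 of 25 members rose and ERF104 (AT5G61600) fell (the same counts when adjusted over the list alone), while among these 25 the replicate block gave 11 and 3, DESeq2 9 and 2, and library size alone 5 and 6. ERF104 lost its call without BG1 (edgeR adjusted p = 0.0606), and 2 members fell without BG2. The ethylene synthesis genes ACS6 (AT4G11280), ACS2 (AT1G01480) and ACS7 (AT4G26200) rose by 3.48 ± 0.22, 3.32 ± 0.56 and 1.46 ± 0.20, and ERF6 (AT4G17490) by 1.85 ± 0.27. The camera adjusted p was 0.0466, but 0.477 with an estimated correlation and 0.0528 with the replicate block, and the list median of 0.31 flipped to -0.011 with library size alone. In the jasmonate list 2 of 21 members rose, LOX4 (AT1G72520, 2.22 ± 0.39) and AOC3 (AT3G25780, 1.03 ± 0.28), and JAR1 (AT2G46370) fell by 0.76 (1 rose and 1 fell when adjusted over the list alone; 2 fell without CM3). AOC3 lost its call with library size alone (edgeR adjusted p = 0.0522) and without BG1, BG2, CM2 or CM3 (up to 0.107). With the replicate block 10 members rose and 8 fell, without replicate 3 in both groups 7 rose and 6 fell, and with library size alone 1 rose and 6 fell. The jasmonate list's median (-0.17) and mean (0.19) differed in sign, and its camera adjusted p was 0.961.

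Genes of indolic defence compounds, detoxification and phenylpropanoid synthesis were among the calls. By the share of higher calls over all tested genes, the rises expected in these lists were 3.0, 3.4 and 2.8. In the indolic list 11 of 20 members rose and CYP79B3 (AT2G22330) fell (12 and 1 when adjusted over the list alone; 16 and 2 with the replicate block), with a median of 2.01 (camera adjusted p = 7.48e-06, and 0.455 with an estimated correlation). CYP79B3 lost its call with limma-voom (adjusted p = 0.0638), with no low-count filter (0.0654) and without BG2, CM1, CM2 or CM3 (up to 0.136 with edgeR). FOX1 (AT1G26380) rose by 7.07 ± 0.91, CYP71A12 (AT2G30750) by 6.01 ± 0.36 and CYP81F2 (AT5G57220), an enzyme of indole glucosinolate modification, from 0.934 ± 0.632 to 46.6 ± 36.9 CPM. CYP71B15 (AT3G26830), the camalexin synthase gene, was at 30.9 ± 5.46 and 36.4 ± 15.6 CPM (adjusted p = 0.625), and its log2 fold change of 0.24 flipped to -0.11 with library size alone. In the oxidative stress and detoxification list 9 of 23 members rose and 14 did not pass (11 rose when adjusted over the list alone; 1 fell with DESeq2 and 1 without CM3), the risers including ZAT11 (AT2G37430, 6.62 ± 0.33) and GSTF7 (AT1G02920, 5.67 ± 0.73), with a camera adjusted p of 0.0312 and of 0.455 with an estimated correlation. Without BG1 4 members rose, and with the replicate block 11 rose and 4 fell. The median of 0.25 flipped to -0.067 with library size alone, where 6 rose and 4 fell. In the phenylpropanoid list 6 of 19 members rose and CAD4 (AT3G19450) fell (the same counts when adjusted over the list alone), including the entry enzyme gene PAL1 (AT2G37040), from 419.0 ± 248.5 to 2341 ± 1098 CPM, and CCR2 (AT1G80820, 2.36 ± 0.39). The block gave 10 higher and 2 lower members, and 3 rose without BG1 and 2 without BG2, where PAL1 lost its call (edgeR adjusted p = 0.0596). CAD4 lost its call without BG2, BG3, CM1 or CM2 (edgeR adjusted p up to 0.134). The camera adjusted p of 0.0466 became 0.606 with an estimated correlation. CYP71A12 and GSTF7 have near-identical neighbours, so their counts are uncertain where reads could be split between copies.

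Among 29 measured genes linked to cell death, 10 rose and GVPE (AT4G32940) fell (11 and 3 when adjusted over the list alone; 14 and 5 with the replicate block; 2 fell without BG2). By the shares of calls over all tested genes, 4.3 rises and 4.0 falls would be expected. The largest rises were of MLO6 (AT1G61560, 5.41 ± 0.45), from 8.44 ± 0.891 to 358.1 ± 212.2 CPM, and MLO12 (AT2G39200, 5.29 ± 0.33), whose products are known for their role in powdery mildew susceptibility. AVPE (AT2G25940), a vacuolar processing enzyme gene, rose by 2.67 ± 0.44 from 0.191 ± 0.109 CPM, and MLO2 (AT1G11310) by 2.06 ± 0.51, a call lost without BG1 (edgeR adjusted p = 0.0774) or BG2 (0.0801). The metacaspase gene MC1 (AT1G02170), a promoter of cell death, rose from 46.8 ± 5.92 to 102.5 ± 23.2 CPM (1.13 ± 0.18, adjusted p = 0.00479). BI1 (AT5G47120), the Bax inhibitor gene that restrains cell death, was at 130.7 ± 17.0 in BG and 156.9 ± 12.3 CPM in CM (adjusted p = 0.177, and 0.0219 with the replicate block), and the sign of its change flipped with library size alone (-0.054). KTI1 (AT1G73260), a protease inhibitor gene, had no read in any library. The camera adjusted p was 0.0466 with a preset correlation, 0.455 with an estimated correlation and 0.0528 with the replicate block. The median of 0.21 flipped to -0.12 with library size alone, where 8 rose and 7 fell. The camera calls of the cell death, ethylene and phenylpropanoid lists were also lost without BG1, BG2 or CM3 (adjusted p from 0.0517 to 0.147).

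Nuclear photosynthesis genes fell. By the share of lower calls over all tested genes, 3.4 falls would be expected in this list. The falls expected in the cell cycle and abscisic acid lists below were 3.9 and 2.6. Of 25 measured members, 15 fell and 10 did not pass (18 fell when adjusted over the list alone, 22 with the replicate block and 22 with library size alone), with a median of -0.68 (camera adjusted p = 9.83e-07, and 0.455 with an estimated correlation). The antenna genes LHCB2.1 (AT2G05100) and LHCB2.2 (AT2G05070) fell from 33.5 ± 12.3 to 8.47 ± 2.71 and from 15.9 ± 5.88 to 4.18 ± 1.61 CPM, and as near-identical copies their separate values are uncertain. Without BG2 or without CM1, 7 members fell. Of 28 cell cycle genes, 11 fell and 2 rose (12 and 3 when adjusted over the list alone), with 20 and 4 under the replicate block and 19 and 1 with library size alone. CYCA1;1 (AT1G44110) fell from 26.5 ± 8.04 to 4.78 ± 1.64 CPM, whereas the cyclin gene CYCB2;1 (AT2G17620) rose from 10.04 ± 0.9495 to 38.3 ± 15.8 CPM. The list's camera adjusted p was 0.00487, and 0.455 with an estimated correlation; 7 members fell without BG1 and 4 without BG2. The other riser, CDC20.1 (AT4G33270), lost its call with library size alone (edgeR adjusted p = 0.229) and without BG1, BG3, CM2 or CM3 (up to 0.0916). In the abscisic acid and osmotic list 7 of 19 members fell and 1 rose (8 and 1 when adjusted over the list alone), with 12 and 2 under the replicate block, 3 lower without CM2 and 2 higher without BG2. HAI1 (AT5G59220), a phosphatase gene of abscisic acid signalling, fell by 2.04 (a call lost without CM2, edgeR adjusted p = 0.0594), and CYP707A3 (AT5G45340), an abscisic acid-degrading enzyme gene, rose by 2.05 ± 0.30. This list's camera adjusted p was 0.0438, but 0.477 with an estimated correlation and 0.268 with library size alone, and from 0.0590 to 0.0992 without BG1, CM2 or CM3.

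**Figure D4:**
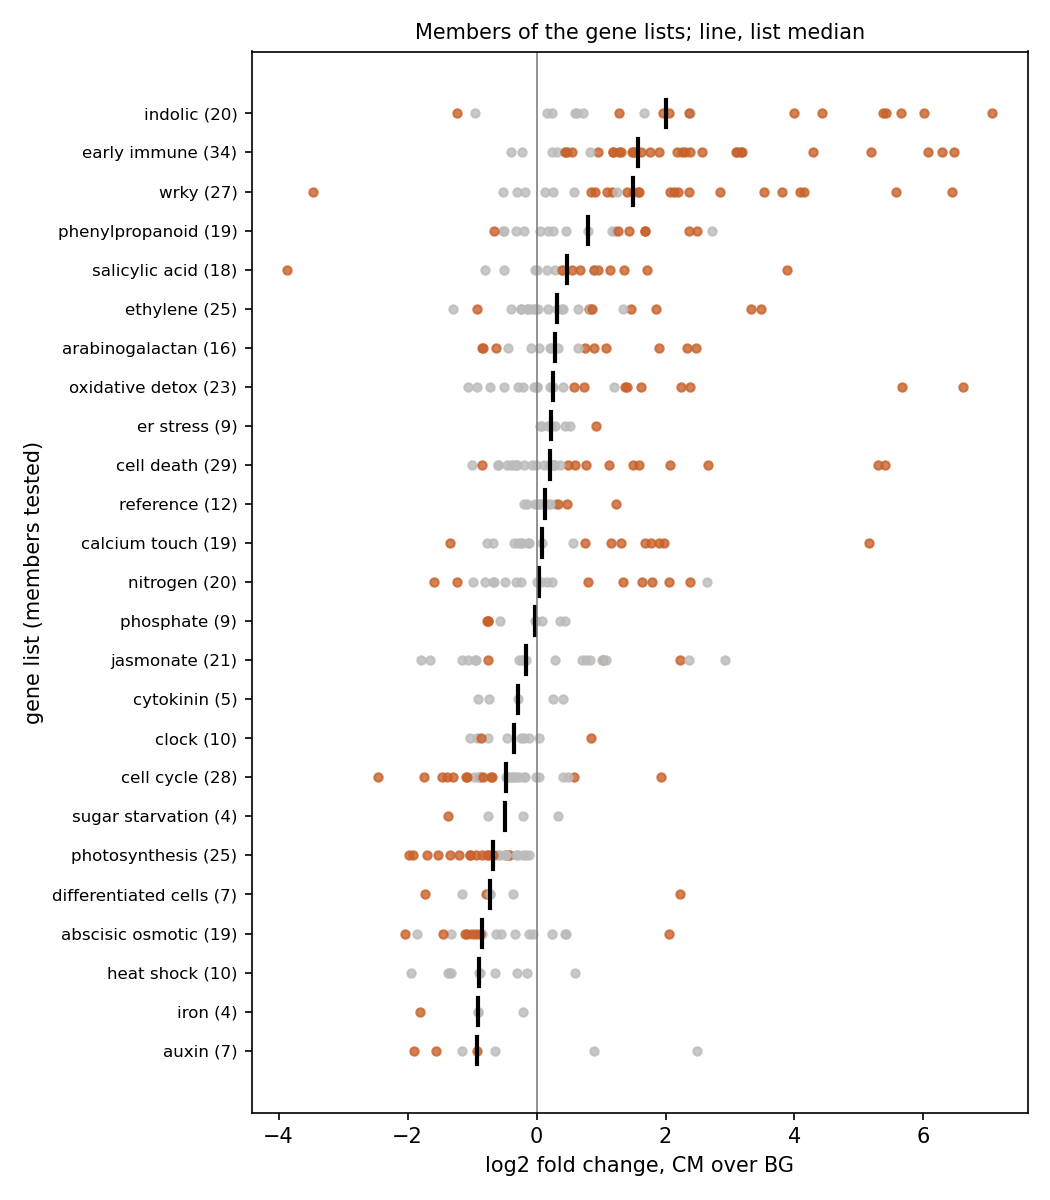
Log2 fold change of CM over BG for each tested member of the 25 gene lists (points, orange where the adjusted p is under 0.05, grey otherwise) with the list median as a black line, numbers in brackets giving the members tested. The highest median is that of the indolic list, at 2.01.

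Other lists did not pass the camera test at an adjusted p under 0.05. Over all tested genes 28.6% were called in either direction, a share against which the counts of these lists should be read. In the calcium and touch list 8 of 19 members rose and CML23 (AT1G66400) fell, with CML42 (AT4G20780) at 5.15 ± 0.90 and XTH18 (AT4G30280) at 1.98 ± 0.22 (9 and 1 when adjusted over the list alone; 9 and 2 with the replicate block). CML23 lost its call without BG1, BG2, BG3 or CM2 (edgeR adjusted p up to 0.0860). The list's median of 0.082 flipped to -0.25 with library size alone, where 8 rose and 6 fell, and its camera adjusted p was 0.105, against 0.0166 with library size alone. Of 16 arabinogalactan protein genes, 6 rose and 3 fell, AGP7 (AT5G65390), FLA1 (AT5G55730) and FLA8 (AT2G45470) (the same when adjusted over the list alone; 7 and 3 with the replicate block; 6 and 4 with library size alone), and 1 fell without BG1 or without BG2. AGP2 (AT2G22470), an abundant transcript, rose from 2634 ± 172.2 to 13223 ± 4487 CPM. The list's median of 0.28 flipped to -0.025 with library size alone, and its camera adjusted p was 0.159, against 0.0264 with library size alone. In the nitrogen list 6 of 20 members rose and NIA1 (AT1G77760) and HHO2 (AT1G68670) fell (the same when adjusted over the list alone), against 4 and 9 with the block, 4 and 5 with library size alone and 3 higher without BG1, BG3 or CM2, and 1 lower without BG1, BG2 or CM3. Its median of 0.037 flipped to -0.27 with library size alone, and its camera adjusted p was 0.608. AMT1;1 (AT4G13510), an ammonium transporter gene, was at 2.06 ± 0.50, a call lost without BG1, BG3, CM2 or CM3. G6PD3 (AT1G24280) was at 2.38 ± 0.72, a call lost with the block (edgeR adjusted p = 0.101), with limma-voom (0.178), with library size alone (0.0510) and without any library but CM3 (up to 0.137).

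The auxin list had 3 of 7 members lower, among them PIN3 (AT1G70940, -1.90 ± 0.35) and PIN7 (AT1G23080, -1.56 ± 0.17), which encode auxin efflux carriers, with 1 higher and 3 lower when adjusted over the list alone and 1 and 4 with the block; 1 was also higher with library size alone, with DESeq2 and without CM1. The higher gene under the list alone and the block was IAA19 (AT3G15540), at 0.358 ± 0.235 and 2.06 ± 1.86 CPM (adjusted p = 0.0502 over all genes, and 0.0228 with the block), and the list did not pass as a whole (camera adjusted p = 0.167, against 0.0296 among genes with at least 1 CPM in 3 libraries). The phosphate list had 3 of 9 lower, SQD2 (AT5G01220, -0.77), PECP1 (AT1G17710, -0.76) and MGD3 (AT2G11810, -0.75), the same when adjusted over the list alone, with 2 higher and 4 lower under the block and 1 higher and 4 lower with DESeq2 (camera adjusted p = 0.312). PECP1 lost its call without BG1, BG2, BG3, CM2 or CM3 (edgeR adjusted p up to 0.110). The iron and sugar starvation lists each had 4 measured members and 1 lower (the same when adjusted over the list alone), OPT3 (AT4G16370, -1.81 ± 0.32) and TPS8 (AT1G70290, -1.37 ± 0.29). With the block 3 iron genes were lower, and 1 sugar starvation gene was higher and 2 lower; with library size alone 2 of each list were lower. FRO2 (AT1G01580), an iron list gene with too few reads for the low-count filter, was called higher with DESeq2 and with edgeR under no such filter. The camera adjusted p was 0.133 for the iron list, against 0.0437 with the block, and 0.312 for the sugar starvation list. The clock list had 1 of 10 higher, TOC1 (AT5G61380, 0.85 ± 0.13), and 1 lower, ELF3 (AT2G25930, -0.86 ± 0.24), the same when adjusted over the list alone, and 6 were lower with the block and 2 with DESeq2 or library size alone (camera adjusted p = 0.529). ELF3 lost its call without BG1, BG2, BG3, CM2 or CM3 (edgeR adjusted p up to 0.113). Of 9 genes of the endoplasmic reticulum stress list, BZIP60 (AT1G42990) rose by 0.93 ± 0.13 (1 also when adjusted over the list alone), and 4 rose with the block. Its median of 0.23 flipped to -0.085 with library size alone, and its camera adjusted p was 0.167, against 0.0248 with the block and 0.0228 without CM3.

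In the heat shock list 0 of 10 members passed with edgeR under TMM, DESeq2 with its default size factors or limma-voom or when adjusted over the list alone, and 0 had an unadjusted p under 0.05, whereas 1 was lower with library size alone in edgeR or DESeq2 and the block gave 1 higher and 5 lower (camera adjusted p = 0.495). In the cytokinin list 0 of 5 passed with edgeR or limma-voom or when adjusted over the list alone, and 1 had an unadjusted p under 0.05 (camera adjusted p = 0.529). Outside those 5, CKX4 (AT4G29740), with too few reads for the filter on all 6 libraries, was called higher with DESeq2, with edgeR under no low-count filter and with edgeR without BG1, BG2, BG3 or CM3; 1 of the 5 was lower with library size alone. Markers of differentiated cell types could be tested for 7 of 29 genes, with MYB46 (AT5G12870) higher at 2.23 ± 0.48 and MYB83 (AT3G08500) and CESA8 (AT4G18780) lower at -1.74 ± 0.36 and -0.78 ± 0.21 (the same when adjusted over the list alone; 3 lower with the block and 4 with library size alone; camera adjusted p = 0.187). The call for CESA8 was lost without any single library (edgeR adjusted p from 0.0611 to 0.0968). Of 12 reference genes, ACT2 (AT3G18780, 1.23 ± 0.28), UBC9 (AT4G27960, 0.47 ± 0.095) and TIP41 (AT4G34270, 0.33 ± 0.10) rose, 2 of them when adjusted over the list alone, and 4 genes rose with the block (camera adjusted p = 0.200). With library size alone 1 reference gene rose and 2 fell, and the list median flipped from 0.12 to -0.21. Without BG1 or without BG2, 1 reference gene rose: ACT2 lost its call (edgeR adjusted p = 0.0634 and 0.0575), and TIP41 lost its call without any single library (from 0.0667 to 0.139). UBC9 lost its call with library size alone (edgeR adjusted p = 0.323).

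Annotation words and gene families drawn from the deposited names and descriptions were enriched among the calls, 66 terms for higher and 26 for lower genes. Of 210 genes described as receptor-like, 76 were higher where 31.2 were expected (one-sided Fisher's exact test, adjusted p = 1.57e-11), and the adjusted p of the other terms named here lay between 1.15e-06 and 0.0120. These tests take genes as independent, whereas the early immune list had an estimated correlation of 0.369 between genes in the fit without the replicate block. The p-values of terms may therefore be too small. Of 29 CRK receptor kinase genes 17 were higher, with CRK41 (AT4G00970) at 5.34 ± 0.25, and of 45 PUB ubiquitin ligase genes 24, with PUB21 (AT5G37490) at 4.47 ± 0.42. Of 12 exocyst genes named ATEXO, 10 were higher, including ATEXO70H1 (AT3G55150) at 3.75 ± 0.34, and of 125 genes described with disease resistance 40 were higher. The mitochondrial NAD family had 9 of 11 entries higher, where carry-over of RNA without poly(A) tails cannot be told apart from a response. Entries such as NAD5A and NAD5C share a gene number, so the 11 may not be separate genes. Among the lower genes, 10 of 15 TCP transcription factor genes were called, led by TCP10 (AT2G31070) at -3.29 ± 0.25, together with 8 of 13 DOF genes, with DOF5.3 (AT5G60200) at -3.33 ± 0.40, and 16 of 46 genes described as kinesin.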

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

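All settings here were planned before the data were examined except 4 chosen after seeing them: leaving out organelle and small RNA genes, DESeq2 with library-size factors, the replicate block with library size only, and leaving out replicate 3 in both groups. The 5111 calls (2653 higher, 2458 lower) became 7873 (1677 and 6196) with library size only, 8349 (6502 lower) with DESeq2 under library-size factors, 8716 (4198 and 4518) with the replicate block and 11651 (9352 lower) with the replicate block and library size only. Limma on log2(FPKM + 1) gave 1633 higher and 5977 lower, and on log2(FPKM + 0.1) 1624 and 5925; FPKM is itself scaled by library totals. An adjusted p under 0.01 left 2439 (1446 and 993), and a log2 fold change of at least 1 left 2563 (1416 and 1147). Leaving out single libraries gave 1524 (without CM2) to 2166 lower calls, and of the 5111 called genes 0 changed sign and 3401 to 4104 kept their call. Photosynthesis genes lower numbered 23 with DESeq2 under library-size factors and 25 with the block and library size only, and 7 to 14 without single libraries (15 in the report). Cell cycle genes lower numbered 19 with library size only, 20 with DESeq2 under library-size factors, 20 with the block and 23 with both, and 4 to 10 without single libraries. Lists past the camera threshold numbered 11, against 0 with an estimated correlation (lowest unadjusted p 0.058), and 6 (without BG1) to 11 without single libraries. With fry 17 passed, but fry asks whether a list changed at all, not whether it moved relative to other genes. The ethylene, phenylpropanoid and cell death calls (adjusted p = 0.0466) were lost with DESeq2 size factors (0.0512), that of ethylene also with at least 1 CPM in 3 libraries (0.0578), and those of phenylpropanoid and cell death also with no low-count filter (0.0641). CYP71B15, not called, changed sign with library size only (-0.11), with FPKM (-0.16 and -0.17), with DESeq2 under library-size factors (-0.11), with the block and library size only (-0.16), and without CM3 (-0.10; highest 0.54 without CM2). BI1, not called, was at -0.054 with library size only, with DESeq2 under library-size factors and with the block and library size only, and at -0.053 with FPKM and either pseudocount. LHY, not called in the main fit, ranged from -1.32 to 0.42 without single libraries (0.031 without CM1). With the replicate block LHY was called lower in CM, as given below. The cause of these changes was not tested where the construction of the setting does not give it. The other planned settings kept the total, higher and lower counts of calls over all genes within 1.5 times, while list counts of a few genes moved more. The depth limits calls for genes near 3 reads.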

Other observations

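The tests in this part were chosen after the results were seen. Organelle-encoded genes made a further group that rose. Of 65 plastid-encoded genes tested, 62 rose, with a median log2 fold change of 2.39, and of 66 mitochondrially encoded genes 38 rose, with a median of 1.11. With library size alone 60 plastid genes rose, and 22 mitochondrial genes rose and 1 fell. The mitochondrial ribosomal RNA genes were at 809.7 ± 424.3 CPM by library size in BG and at 4751 ± 2025 in CM (SD, n = 3), while the remaining mitochondrial genes went from 450.7 ± 105.6 to 1017 ± 325.5. LHY, a clock gene expressed in the morning, was at 39.3, 166.6 and 364.2 CPM in BG replicates 1, 2 and 3 and at 25.7, 127.6 and 259.8 CPM in CM replicates 1, 2 and 3 (edgeR adjusted p = 0.00195 with the replicate block, where GI was at 0.000294).

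The real split of the 6 libraries gave 5111 calls by edgeR, and the highest of the other splits gave 0 (1136 genes at an unadjusted p under 0.05, and 0 with limma-voom). Of 10 splits 1 reached the real count, which is too few splits for a share under 0.05. Among the 4 splits that part all 3 pairs, the highest other also gave 0. Every other split has CM and BG libraries on both sides, so their difference widens the spread within each side. Few calls are expected there in advance, so the 0 says nothing about chance.

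Library-size scaling moved the median gene by -0.32 against TMM and made most calls lower. Both scalings work on shares of reads, so this shift is a change in composition, which a fall of all transcripts per cell alike would not give. Leaving out the 19 genes that are among the 10 most abundant of any library left a shift of -0.28, and leaving out organelle genes left -0.32, so neither group of transcripts accounts for most of it. The 575 genes called higher by at least 4-fold took 2.45% ± 0.339 of reads in BG and 11.6% ± 2.77 in CM (SD, n = 3). This by itself shifts the other genes by -0.14. All genes called higher took 16.8% and 35.2%, a larger change that would shift the remaining genes further, by an amount not given here. Both sets were chosen by their TMM fold changes and calls, so these shares are not independent of the scaling. No spike-in was analysed, so amounts per cell are not known here.

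The rise of organelle transcripts may come from carry-over of RNA without poly(A) tails. Nuclear structural RNAs, which lack such tails, were at 1.84-fold in mean share, with the lowest CM share at 0.635 of the highest BG share. They had 44 to 59 reads in BG libraries and 148, 111 and 42 in CM1, CM2 and CM3. Mitochondrial transcripts took 0.710%, 0.714% and 0.306% of reads in CM1, CM2 and CM3. Rows with ENSRNA identifiers, which include the structural RNAs, took 0.00228% ± 0.000285 of reads in BG and 0.00358% ± 0.000687 in CM (SD, n = 3). Every CM library lay above every BG library in that share. Small nucleolar RNAs, with 673 to 1266 reads per library, were at 1.05-fold and nuclear transfer RNAs at 1.04-fold. These classes go different ways, and without strand their reads were not separated from those of any overlapping genes. Carry-over can therefore not be told apart from a response. Scaling alone is argued against, since the mitochondrial genes other than ribosomal RNA kept a median of 0.79 under library size only, above the -0.32 shift between scalings. A response of the organelles to conditioned medium stays open and was not tested.

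Clock genes could not decide whether time of day explains the fall of nuclear photosynthesis genes. The difference of LHY and GI in log2 spanned 5.07 in BG and 5.13 in CM but differed by 0.24 between groups. A straight line within groups had a slope of 0.0259 ± 0.0435 (SE). It predicts a change of 0.00618 ± 0.0104 (SE from the slope only) against the observed median of -0.68. The list was highest in replicate 2 of both groups, at the middle value of the LHY and GI difference, which such a line misses. A change shared by LHY and GI would cancel in their difference. Same-numbered libraries of BG and CM lay close in it, at -0.30 and -0.18, 2.08 and 2.50, and 4.78 and 4.95. Pairs 1, 2 and 3 each showed a fall, with medians of -0.61, -0.58 and -0.95. Scaling as the whole cause is argued against, since a scaling factor moves all genes alike and the list median lay below that of all tested genes by a mean log2 difference of -0.68 ± 0.19 (SD, n = 3 pairs). An effect of conditioned medium on these genes is a hypothesis that these data alone cannot establish.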
